A study of Homo sapiens with 8 samples.

How the data were processed

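Ribosome footprints of 8 libraries were analysed: HDF whole cells (B1, B2), HDF focal adhesions (B1, B2, B1_2) and HUVEC focal adhesions (B1, B2, B1_2). Per the labels, actively translating ribosomes were captured with a RiboLace kit from cells treated with cycloheximide, and focal adhesions were isolated from cells on fibronectin with a low ionic triethanolamine buffer and hydrodynamic removal of cell bodies. The deposited values are expected counts over coding sequences, made by the authors per the submitters' processing notes after alignment with STAR to GRCh38, without a stated version. Trimming, rRNA removal, PCR duplicates and how reads shared by several transcripts were divided are not given in the sources used here. Whole cell and focal adhesion libraries came in separate tables with the same features.

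The tables held 89162 transcript rows of 19693 genes, 15234 of them with several rows, and whole values made up between 76.5% and 87.8% of the nonzero entries. All rows of a library summed to between 4.09 and 4.55 times its deposited total, so reads were repeated over transcripts. Therefore the transcript with the highest total stood for its gene, which gave between 99.8% and 101.0% of the deposited total, and values were rounded. For privacy 64 Y-linked, XIST and HLA genes were left out, and 19629 genes remained, of which 19005 symbols matched the RefSeq table of GRCh38.p14. Depth per library is given in the report. The CPM of 3 counts was 32.4 and 1.16 in HDF whole cells B1 and B2, 12.0, 14.2 and 4.03 in HDF focal adhesions B1, B2 and B1_2, and 5.49, 5.16 and 38.8 in the same order in HUVEC. Between 3067 and 11580 genes had at least 5 counts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and plots.

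B1 and B1_2 of a group were summed, so each group had 2 units. Counts were normalised with TMM, filtered with filterByExpr (minimum count 10) and fitted with a robust quasi-likelihood model in edgeR 4.0.16 (R 4.3.3) with all 3 groups in 1 fit, which left 3 residual degrees of freedom. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. The SE of a log2 fold change is its absolute value divided by the square root of the quasi-likelihood F statistic. It rests on a spread moderated across genes and fitted over all groups in the fit, not on the units of the compared groups alone. The 2 comparisons, the tests, the units, the 29 gene lists, the rule for named genes and the first set of other settings were chosen before the data were examined. The 26 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with the correlation estimated and with fry, adjusted over the lists of a comparison. The smallest p of an exact permutation test of 2 against 2 units is 0.33, so none is used.

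Named genes were, per comparison, the 10 with the largest absolute log2 fold change in each direction among called genes with every library of 1 group on the same side of the other and a mean of at least 20 CPM in the higher group. To these were added up to 3 members of each list with the smallest adjusted p, 13 genes fixed by name (such as G3BP1 and VCL), and the 10 most abundant genes of each group. Where a group had no counts the fold is a bound against a floor of 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% interval.

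The other settings chosen then were DESeq2 size factors, library totals, the Wald test of DESeq2 1.42.0, limma-voom, no filter, at least 50 counts in every unit of a group, only the 2 groups compared, the replicate number as a block, 3 separate samples, the unit as a random block, B1_2 left out, thinning to 92724 counts, transcripts of a gene summed, and each unit left out in turn. After the data were seen, regrouped units (B1 with B2, against B1_2), the mean of both focal adhesion groups and the coding length trend were added. For the latter a loess curve of log2 fold change on the logarithm of coding length (span 0.5, lengths held within percentiles 1 and 99) was added as an offset to the HDF focal adhesion units and the test was repeated. Of the tested genes 98.5% had a listed length divisible by 3.

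On simulated data with the same depths the fit for HDF focal adhesions against whole cells found 15 of 91 genes changed 4-fold and 69 of 89 changed 16-fold, with 11 unchanged genes called. For HUVEC against HDF focal adhesions it found 30 of 97 and 80 of 100, with 16 unchanged genes called.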

Results

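Ribosome-protected fragments, the stretches of mRNA that a translating ribosome shields from nuclease, were counted over coding sequences in 8 libraries. The cells were human dermal fibroblasts (HDF), connective tissue cells of the skin, and human umbilical vein endothelial cells (HUVEC), which line a blood vessel. HDF were profiled as whole cells in 2 libraries (B1 and B2) and as isolated focal adhesions in 3 libraries (B1, B2 and B1_2). HUVEC were profiled as isolated focal adhesions in 3 libraries with the same numbers. Focal adhesions are the integrin-based contacts between a cell and its substrate, here fibronectin, and were left on the dish after a low-salt shock and a jet of buffer had removed the cell bodies. By its title the series concerns ribonucleoprotein complexes of G3BP1, an RNA-binding protein best known from stress granules, and their part in focal adhesions and migration. The labels do not say what B1_2 is, so B1 and B1_2 of a group were summed and every group held 2 units (n = 2). Nothing in the labels says that units came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

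Gene-level totals were 92724 counts in HDF whole cell B1 and 2585744 in B2. The HDF focal adhesion libraries held 249751 (B1), 211736 (B2) and 744611 counts (B1_2), and the HUVEC focal adhesion libraries 546311, 581895 and 77384. A floor of 3 counts corresponded to 32.4 in HDF whole cell B1, 38.8 in HUVEC B1_2 and 1.16 in HDF whole cell B2 CPM. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules. B1 and B2 of HDF focal adhesions were nearly interchangeable: chi-square over degrees of freedom was 1.065 over the 381 genes with at least 200 counts (p = 0.185) and 1.083 over 4402 genes with at least 20 counts (p = 7.68e-05). Against B1_2 the same ratio was 17.79 for B1 and 16.31 for B2 at 200 counts. B1 and B2 therefore agree within sampling noise among abundant genes and could not be told from 1 library read again, so counts of genes are also given with both counted as 1 sample against B1_2 ("regrouped"). For HUVEC B1 against B2 the ratio was 3.821 over 1085 genes with at least 200 counts, and against B1_2 it was 23.17 for B1 and 24.18 for B2. From the least to the most abundant genes the ratio of HUVEC B1 against B2 hardly changed (3.523, 3.65 and 3.688). Because reads are not independent molecules, a ratio above 1 cannot decide whether HUVEC B1 and B2 are separate samples or 1 library.

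Cell identity was clear in 7 of the 8 libraries. COL1A1 and COL1A2, the chains of type I collagen, reached 17385 and 8406 CPM in HDF whole cell B1 and lay between 6980 and 7786 and between 3288 and 4091 CPM in the HDF focal adhesion libraries. The library labelled HDF whole cell B2 held COL1A1 at 0.373 CPM and COL1A2 at 1.49 CPM. It held the endothelial cadherin CDH5 at 558 CPM, the junction protein PECAM1 at 739 CPM and the receptor TIE1 at 906 CPM. In the HUVEC focal adhesion libraries CDH5 lay between 985 and 1064 CPM, whereas all 3 HDF focal adhesion libraries had 0 counts. The endothelial list took 1.15% of the counts of the library labelled HDF whole cell B2, 0.0679% of whole cell B1, between 0.0416% and 0.0641% of HDF focal adhesions and between 1.21% and 1.33% of HUVEC focal adhesions. The fibroblast list took 0.198% of that library, 3.84% of whole cell B1, between 1.83% and 2.02% of HDF focal adhesions and between 0.223% and 0.259% of HUVEC focal adhesions. Across 5087 genes, which are not independent replicates, log2 CPM of the library labelled HDF whole cell B2 correlated at r = 0.68 and 0.684 with HUVEC focal adhesions B1 and B2. With HUVEC B1_2 (r = 0.56) it correlated no better than with HDF whole cell B1 (0.561). HUVEC B1_2, the library with the fewest counts, reached only 0.797 and 0.8 with HUVEC B1 and B2. HDF whole cell B1 shares compartment and deposited table with B2, so these 2 values say little on cell identity. Keratinocyte, melanocyte, and leukocyte and red cell markers took at most 0.0375%, 0.00259% and 0.0222% of any library.

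**Figure D1:**
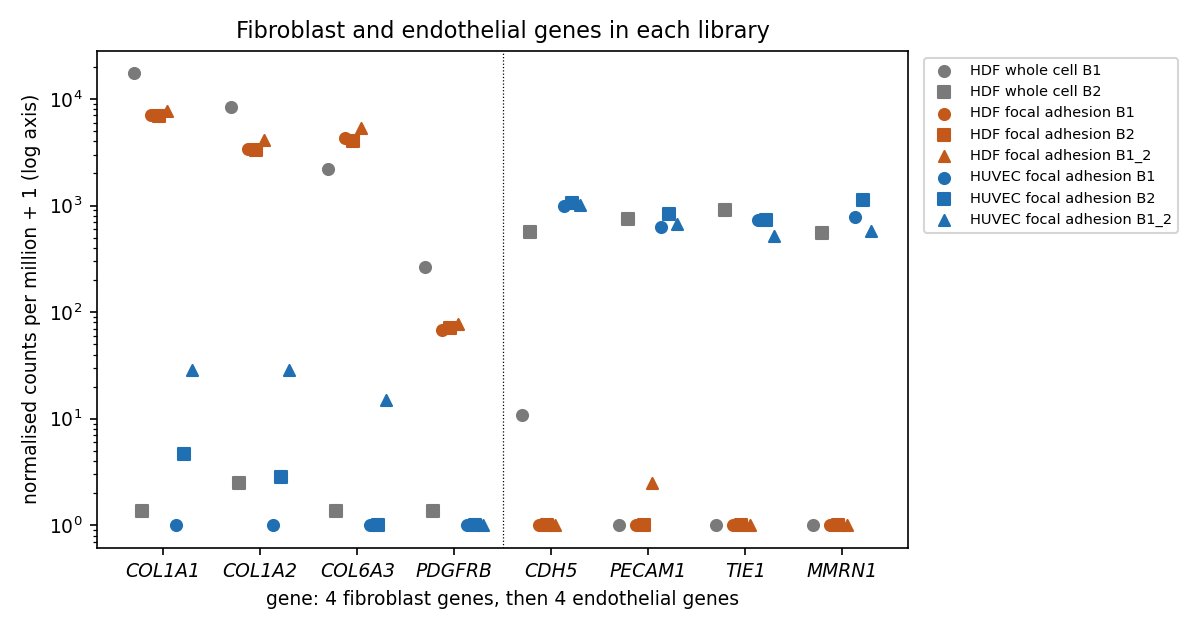
Normalised CPM plus 1 (log axis) of 4 fibroblast and 4 endothelial genes, with 1 point per library, colour for the group and shape for the library number. The library labelled HDF whole cell B2 (grey squares) lies with the HUVEC libraries for all 8 genes, for example 558 CPM of CDH5 against 9.73 CPM in HDF whole cell B1.

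The first comparison asked which mRNAs carried more or fewer ribosome footprints at HDF focal adhesions than in the libraries labelled HDF whole cells. Of these, B2 carried endothelial and lacked fibroblast transcripts, so B1 alone gave a whole cell reference with a fibroblast profile. Cell type and compartment therefore cannot be told apart wherever a result rests on B2. The clearest loss was of the mRNAs translated inside mitochondria: all 13 mitochondrially encoded genes were lower in HDF focal adhesions, and their share of counts was between 6.90% and 7.11% in whole cells and between 0.415% and 0.820% at focal adhesions. MT-CO1, a subunit of cytochrome oxidase, had a log2 fold change of -3.34 ± 0.34 (SE, n = 2 units), from between 17035 and 20751 CPM to between 1390 and 2240 CPM. Of the cholesterol synthesis, histone and glycolysis lists 10 of 21, 23 of 24 and 10 of 18 genes were higher. With an estimated correlation none of these lists passed camera (adjusted p = 0.186, 0.120 and 0.186). SCD, the desaturase that makes monounsaturated fatty acids, rose by 5.39 ± 0.51 (419 to 490 CPM against 8.94 and 19.5 CPM). The 19.5 CPM, in HDF whole cell B1, lay under that library's floor of 32.4 CPM for 3 counts. FN1, which encodes fibronectin, was higher by 2.64 ± 0.34 (9853 to 16149 CPM against 1705 and 2228 CPM).

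In edgeR's quasi-likelihood fit of all 3 groups, 400 of 8826 genes were higher and 520 lower at HDF focal adhesions (adjusted p under 0.05). With the library labelled HDF whole cell B2 left out the counts were 638 and 421, without whole cell B1 1327 and 1476, and regrouped 156 and 185. Of the 400 and 520 genes, 310 and 226 passed in the same direction both without whole cell B1 and without whole cell B2. No gene passed without either HUVEC unit or without HDF focal adhesion B1, where 1000 higher and 1458 lower (without HUVEC B1), 999 and 1457 (without HUVEC B2) and 608 and 548 genes (without HDF focal adhesion B1) had an unadjusted edgeR p under 0.05. Without HDF focal adhesion B2, 14 and 10 genes passed. Of the genes named below that passed, the calls of APLN, CDH11, CHD3, G3BP2, IFI27, ITGB4, KANK2, MLPH, P4HA1, PLCL1, PUM2, RPLP0, RPS12, SERPINF1, SOX7, SOX18, THBS1 and TMSB10 ended regrouped (edgeR adjusted p between 0.0508 and 0.112). CFAP54 and FEZF2 were not tested regrouped. The fit of 3 groups takes part of its spread from HUVEC units outside this comparison. In the fit of only the 2 groups compared, also chosen before the data were examined, 125 of 8129 genes were higher and 217 lower. Of these, 116 and 205 were among the 400 and 520 genes, and 29 named genes kept direction but no longer passed. Whole cells and focal adhesions were deposited in separate tables, so compartment and sequencing run cannot be told apart, and all fold changes are relative to the other transcripts of a library. Scaling by library totals alone moved the median log2 fold change of all genes from -0.09 to -0.22.

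Fold changes also followed coding length. In 5 equal bins from the shortest to the longest genes, with median coding lengths of 549, 1020, 1500, 2226 and 3912 bases, the median log2 fold change was 0.64, 0.12, -0.08, -0.35 and -0.90. Spearman's rho across 8826 genes was -0.371, and -0.269 without the library labelled HDF whole cell B2. Tested relative to this trend, a choice made after the data were seen, 327 genes were higher and 217 lower, of which 216 and 205 were among the 400 and 520 genes. Of the 310 and 226 genes that passed without each whole cell library, 188 and 117 also passed relative to the length trend. Besides those said below to have ended, the calls of CFAP54, INSC, ITGB4 and PLCL1 ended relative to this trend (edgeR adjusted p between 0.0554 and 0.0912). Their log2 fold changes, fitted with 0 counts in 1 group, hardly moved: from -8.85 ± 1.93 to -8.65 ± 2.31, from 7.64 ± 1.95 to 7.82 ± 1.94, from -8.72 ± 2.07 to -8.55 ± 2.40 and from -9.58 ± 1.98 to -9.46 ± 2.17. With 0 counts in 1 group a fitted value depends little on the length offset, so these values cannot decide whether coding length plays a part. Fitted sizes also moved with the whole cell library used. Without B1 and without B2 the log2 fold change was 2.37 and 3.80 for DIAPH1, 1.63 and 2.80 for HSPD1, -4.32 and -2.40 for ITGB3, 2.08 and 3.78 for NDUFS5, 2.04 and 3.08 for P4HA1, and 5.68 and 4.49 for SCD. In whole cell B1, NDUFS5 (9.73 CPM), P4HA1 and SCD (19.5 CPM each) lay under the 32.4 CPM of 3 counts. DIAPH1 (77.8 CPM), HSPD1 and ITGB3 (87.6 CPM each) lay not far above it. The values without B2 therefore rest on few counts, and part of these moves may be counting error. Below, list shifts are medians of the list minus the median of all genes, tested with camera at a preset correlation of 0.01.

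Mitochondrially encoded genes shifted at -3.14 (camera adjusted p = 1.39e-22; adjusted p = 0.186 with an estimated correlation), and all 13 fell as well when adjusted over the list alone. MT-CO3 fell by 3.32 ± 0.32 and MT-ND4L, a subunit of complex I, by 4.75 ± 0.45 on the log2 scale. Their shift was -3.13 or lower without either whole cell library and -3.43 relative to genes of the same coding length. Reads of these genes can be shared with nuclear copies of mitochondrial DNA. Nuclear genes of the respiratory chain moved the other way, with 9 of 47 higher and none lower (14 higher adjusted over the list alone; shift 1.10, camera adjusted p = 1.21e-09; adjusted p = 0.228 with an estimated correlation). NDUFS5, of complex I, was higher by 2.23 ± 0.48, a call that ended relative to genes of its coding length (1.26 ± 0.47, edgeR adjusted p = 0.132). Their list has short coding sequences, with a median of 507 bases, and its shift was 0.57 relative to genes of the same length, with 2 genes higher.

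Of 21 cholesterol synthesis genes 10 were higher, 0 lower and 11 did not pass, with 17 higher adjusted over the list alone (shift 2.32, camera adjusted p = 1.13e-13; adjusted p = 0.186 with an estimated correlation). MSMO1, a sterol demethylation enzyme, was higher by 3.78 ± 0.60 and FDFT1, squalene synthase, by 2.59 ± 0.38. All 30 whole cell counts of MSMO1 lay in the library labelled HDF whole cell B2, so the size of its change rests on that library. The shift relative to genes of the same coding length was 2.59, with 12 genes higher. Of 18 glycolysis genes 10 were higher (13 adjusted over the list alone; shift 1.47, camera adjusted p = 1.25e-08; adjusted p = 0.186 with an estimated correlation). The glucose transporter gene SLC2A1 was higher by 3.02 ± 0.46, LDHA, lactate dehydrogenase, by 1.99 ± 0.31 and ENO1, enolase, by 2.01 ± 0.33.

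Replication-dependent histones, whose mRNAs are made in S phase and lack a poly(A) tail, were higher for 23 of 24 genes, also adjusted over the list alone (shift 2.03, camera adjusted p = 5.09e-20; adjusted p = 0.120 with an estimated correlation). H2AC6, H2AC11 and H2AC14 were higher by 2.23 ± 0.32, 2.25 ± 0.32 and 2.65 ± 0.38. Their coding sequences are the shortest of any list, with a median of 388.5 bases, and relative to genes of that length the shift was 1.13 with 6 genes higher. Levels of single histone genes are uncertain because the copies share reads. Among 36 proliferation genes 14 were higher (19 higher and 1 lower adjusted over the list alone; shift 1.27, camera adjusted p = 1.64e-10; adjusted p = 0.228 with an estimated correlation). TK1, thymidine kinase, was higher by 2.40 ± 0.51, RRM1, a subunit of ribonucleotide reductase, by 2.01 ± 0.36 and CCNB1, cyclin B, by 1.67 ± 0.35.

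The list of endoplasmic reticulum (ER) translocation, folding and secretion had 16 of 51 genes higher and none lower, and 32 higher adjusted over the list alone (shift 1.04, camera adjusted p = 8.11e-12; adjusted p = 0.228 with an estimated correlation). DAD1, a subunit of the oligosaccharyltransferase, was higher by 2.56 ± 0.38, SPCS3, of the signal peptidase, by 2.13 ± 0.36 and SSR3, of the translocon, by 1.90 ± 0.34. Of the caveolae and endocytosis list 7 of 25 were higher and 2 lower (9 and 3 adjusted over the list alone; shift 0.98, camera adjusted p = 8.29e-04; adjusted p = 0.292 with an estimated correlation). CAV1, which builds caveolae, was higher by 2.43 ± 0.35 and ANXA2, a membrane-binding annexin, by 2.59 ± 0.33. S100A6, a calcium-binding protein, was higher by 1.93 ± 0.31, a call that ended relative to genes of its coding length (0.84 ± 0.30, edgeR adjusted p = 0.123).

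**Figure D2:**
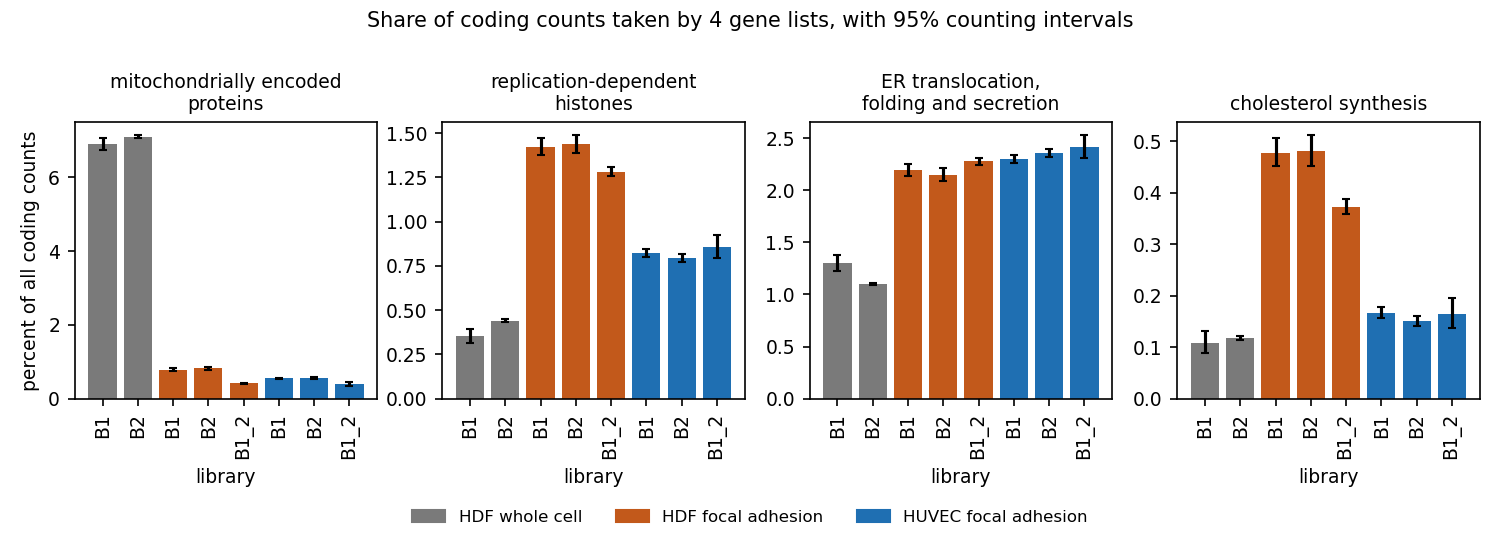
Percent of all coding counts taken by 4 gene lists in each library (bars, with 95% exact binomial intervals that cover counting error only), coloured by group. Mitochondrially encoded genes took 6.90% and 7.11% of the whole cell libraries and at most 0.820% of any focal adhesion library, and the other 3 lists took larger shares in all HDF focal adhesion libraries than in both whole cell libraries.

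Cytoskeletal lists were mixed. Of 39 actin and actomyosin genes 7 were higher and none lower, against 8 and 1 adjusted over the list alone (shift 0.74, camera adjusted p = 1.12e-04; adjusted p = 0.371 with an estimated correlation). DIAPH1, a formin that elongates actin filaments, was higher by 2.73 ± 0.45 and CNN3, a calponin, by 2.07 ± 0.37, while TMSB10, a thymosin that was higher by 1.55 ± 0.34, did not pass relative to genes of its length (0.43 ± 0.34, edgeR adjusted p = 0.479). Microtubules and motors had 5 of 29 genes higher and 1 lower, also adjusted over the list alone (shift 0.74, camera adjusted p = 0.0129; adjusted p = 0.292 with an estimated correlation), among them the tubulin gene TUBB4B (1.87 ± 0.35), which shares reads with its paralogs. Intermediate filaments and linkers had 2 of 12 higher (5 higher and 2 lower adjusted over the list alone; shift 0.94, camera adjusted p = 0.0175; adjusted p = 0.292 with an estimated correlation), including LMNA, which encodes lamin A and C, at 1.67 ± 0.31.

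For the adhesion machinery camera found no shift, although the focal adhesion core list took between 2.23% and 2.39% of counts in HDF focal adhesions and 1.53% and 1.66% in whole cells. Of 52 focal adhesion core genes 4 were higher, 3 lower and 45 did not pass (4 and 5 adjusted over the list alone; camera adjusted p = 0.921), and its median (0.09) and the direction of the test differed in sign, as they did for the integrins. PTK2, focal adhesion kinase, fell by 2.49 ± 0.45 (35 to 75 CPM against 204 and 368 CPM) and the tensin gene TNS1 by 1.82 ± 0.35. The call for TNS1 ended relative to genes of its coding length (-0.83 ± 0.34, edgeR adjusted p = 0.169). FBLIM1, a filamin-binding protein, fell by 2.23 ± 0.47, a call that ended without the library labelled HDF whole cell B2 (-1.31 ± 0.64, edgeR adjusted p = 0.195). Vinculin (VCL, 0.71 ± 0.31), talin (TLN1, 0.80 ± 0.32), zyxin (ZYX, 0.40 ± 0.30), paxillin (PXN, -0.95 ± 0.41), the integrin gene ITGB1 (0.42 ± 0.30) and beta-actin (ACTB, 0.86 ± 0.32) did not pass, with edgeR adjusted p between 0.108 and 0.409. The change of TLN1 was 1.11 ± 0.25 without the library labelled HDF whole cell B2. TLN1 passed relative to genes of its long coding sequence (1.94 ± 0.33, edgeR adjusted p = 0.0173), as did VCL (1.41 ± 0.31, edgeR adjusted p = 0.0339). For ITGB1 no such value is given, because its listed coding length of 24989 bases is not divisible by 3. Without whole cell B1 the changes were 0.79 ± 0.27 for VCL, 0.66 ± 0.25 for TLN1, 1.24 ± 0.26 for ACTB and -1.24 ± 0.28 for PXN. The only reference was then the library labelled HDF whole cell B2, which carried endothelial transcripts, so cell type and compartment cannot be told apart there. Of 11 integrins 1 was higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.921), the latter including ITGB3 at -3.81 ± 0.66 (14 to 23 CPM against 88 and 350 CPM). Of 42 extracellular matrix genes 1 was higher, FN1, and 2 were lower, LAMA4, a laminin chain (-2.01 ± 0.33), and THBS1, thrombospondin (-1.65 ± 0.35), with the same counts adjusted over the list alone (camera adjusted p = 0.145). The calls for LAMA4 (-1.04 ± 0.33, edgeR adjusted p = 0.0864) and THBS1 (-0.94 ± 0.35, 0.130) ended relative to genes of their length.

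G3BP1 (chromosome 5, 151771954 to 151812785, GRCh38) lay between 340 and 584 CPM at HDF focal adhesions, at 38.9 CPM in whole cell B1 and at 220 CPM in the library labelled HDF whole cell B2. Its log2 fold change was 1.53 ± 0.60 and did not pass (edgeR adjusted p = 0.131), because the 2 whole cell libraries differed. The change was 3.49 ± 0.52 against whole cell B1 alone, where the level lay near the 32.4 CPM of 3 counts, so this size rests on few counts. Against only the library labelled HDF whole cell B2, which carried endothelial transcripts, it was 1.07 ± 0.29. Regrouped, G3BP1 did not pass (edgeR adjusted p = 0.129). Its paralog G3BP2 was higher by 1.51 ± 0.36 (213 to 261 CPM against 77.8 and 84.2 CPM, edgeR adjusted p = 0.0325), a call that ended regrouped (0.0722). Their partner CAPRIN1 had 1.15 ± 0.33 (edgeR adjusted p = 0.0525). Its change was 1.05 ± 0.27 without whole cell B1 and 1.47 ± 0.34 without the library labelled HDF whole cell B2. CAPRIN1 passed relative to genes of its length (1.67 ± 0.33, edgeR adjusted p = 0.0264). Among 46 stress granule and RNA-binding proteins 8 were higher and 2 lower (15 and 5 adjusted over the list alone; shift 0.64, camera adjusted p = 0.00805; adjusted p = 0.306 with an estimated correlation). HNRNPU, which binds nuclear RNA, was higher by 1.81 ± 0.34. The members that fell were PABPC1, the cytoplasmic poly(A)-binding protein (-2.28 ± 0.31; 418 to 514 CPM against 2180 and 2208 CPM), and PUM2, a translational repressor (-1.96 ± 0.42), whose call ended relative to genes of its length (-1.32 ± 0.42, edgeR adjusted p = 0.0898).

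Cytosolic ribosomal proteins did not shift in this fit, with 1 of 77 higher and 2 lower and 0 and 0 adjusted over the list alone (camera adjusted p = 0.140). RPLP0 and RPS12, whose levels share reads with pseudogenes, fell by 1.25 ± 0.33 and 1.20 ± 0.32 on the log2 scale. Relative to genes of their short coding length the list was lower (shift -0.47, camera adjusted p = 1.83e-04), with 4 genes lower, and without the library labelled HDF whole cell B2 its shift was -0.38 (camera adjusted p = 0.00957; adjusted p = 0.322 with an estimated correlation, which was not tried relative to coding length). Translation factors had 4 of 39 higher and 1 lower (9 and 1 adjusted over the list alone; shift 0.54, camera adjusted p = 0.0133; adjusted p = 0.228 with an estimated correlation). The member that fell was EIF4G2, an initiation factor of the eIF4G family (-1.98 ± 0.34). Proteasome genes shifted by 0.99 (camera adjusted p = 2.30e-06; adjusted p = 0.228 with an estimated correlation) with 1 of 31 higher, tRNA synthetases by 0.63 (camera adjusted p = 0.0196; adjusted p = 0.228 with an estimated correlation) with 1 of 23 higher, and for both 0 passed when adjusted over the list alone. Immediate early and heat shock genes had 6 of 33 higher (9 higher and 2 lower adjusted over the list alone; shift 0.59, camera adjusted p = 0.00837; adjusted p = 0.228 with an estimated correlation), including the chaperones HSP90AA1 (1.80 ± 0.36), HSP90AB1 (1.64 ± 0.36) and HSPD1 (1.91 ± 0.42).

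Chromatin and nuclear factors, the list with the longest coding sequences (median 6930 bases), had 1 of 30 higher and 9 lower (1 and 14 adjusted over the list alone; shift -0.71, camera adjusted p = 0.00115; adjusted p = 0.371 with an estimated correlation). CHD3, a chromatin remodeller, fell by 2.09 ± 0.37 and MED13, of the Mediator complex, by 2.48 ± 0.44. Relative to genes of the same length the shift turned to 0.41 (camera adjusted p = 0.0969), with 3 higher and 0 lower, so that the calls of CHD3 (-1.04 ± 0.36, edgeR adjusted p = 0.115) and MED13 (-1.42 ± 0.43, 0.0800) ended. AHNAK, a very large scaffold protein of the cell cortex as well as the nucleus, was higher by 2.44 ± 0.37 (15782 to 21972 CPM against 2306 and 4240 CPM).

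Protrusion-localised RNAs had 4 of 17 higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.115), including KANK2, an adaptor at adhesion borders (2.86 ± 0.65; 745 to 792 CPM against 204 and 44.7 CPM), P4HA1, a collagen prolyl hydroxylase (2.21 ± 0.47), and the receptor gene TNFRSF12A (2.12 ± 0.38). The change of KANK2 was 4.16 ± 0.33 without whole cell B1 and 1.90 ± 0.34 without the library labelled HDF whole cell B2. The calls for KANK2 (edgeR adjusted p = 0.0508) and P4HA1 (0.0619) ended regrouped. That for TNFRSF12A ended relative to genes of its length (1.29 ± 0.38, edgeR adjusted p = 0.0699). Interferon-stimulated genes had 0 of 11 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.921), and both of these, BST2 and IFI27, had counts only in the library labelled HDF whole cell B2. Median and mean differed in sign for this list and for smooth muscle and pericyte markers. Smooth muscle and pericyte markers had 1 of 8 higher, also over the list alone (camera adjusted p = 0.145). Of 22 fibroblast markers 0 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.115). MMP2, a matrix metalloproteinase, fell by 2.83 ± 0.41 (55 to 205 CPM against 772 and 963 CPM) and CDH11, a mesenchymal cadherin, by 1.53 ± 0.34, a call that ended regrouped (edgeR adjusted p = 0.0556) and relative to genes of its length (-1.10 ± 0.33, 0.0799). Of 26 endothelial markers 0 were higher and 7 lower (1 and 10 adjusted over the list alone; camera adjusted p = 8.57e-06; adjusted p = 0.477 with an estimated correlation), and this loss rests on the library labelled HDF whole cell B2, since 1 of the 7 passed without it. SOX18 (at least 26.7-fold lower), SOX7 (1 count against 204) and APLN (1 against 86) were among those that did not.

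**Figure D3:**
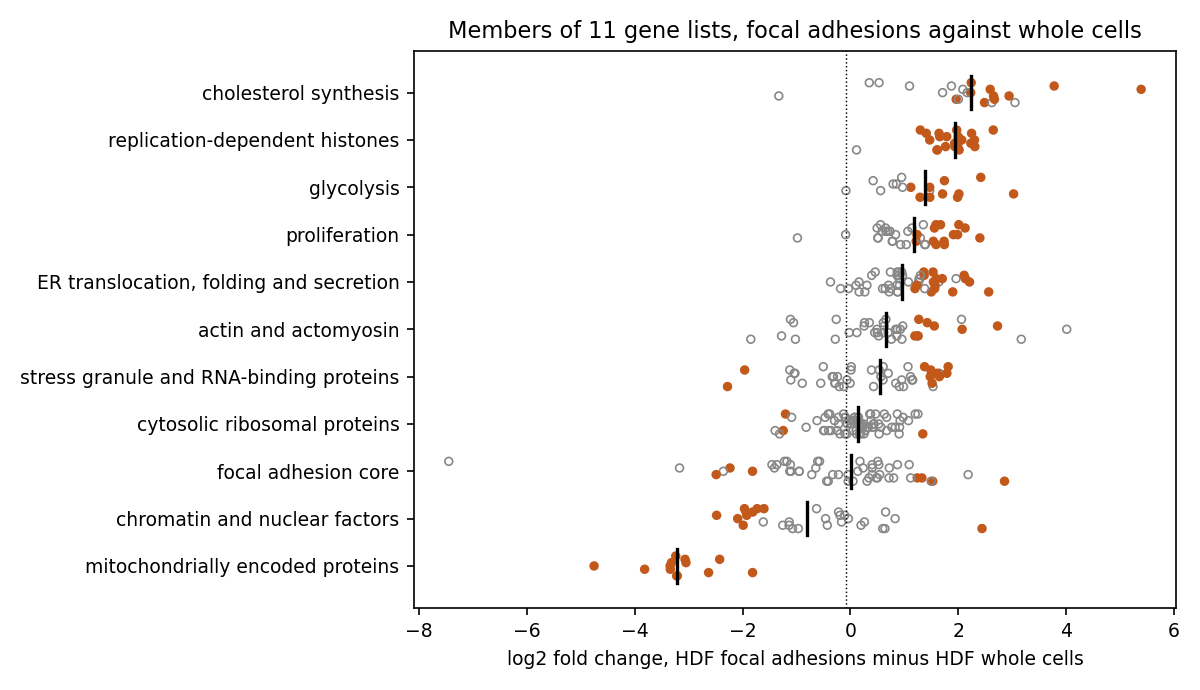
Log2 fold change of each member of 11 gene lists between HDF focal adhesions and HDF whole cells (points, filled where edgeR's adjusted p was under 0.05), with the median of each list (bar) and the median of all genes (dotted line). The 13 mitochondrially encoded genes lie furthest to the lower side, and 23 of the 24 histone genes and SCD, at 5.39, lie on the higher side.

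Among the single genes with the largest changes, WNT5B, a secreted Wnt ligand, had 140 counts at HDF focal adhesions and 0 in whole cells (at least 104-fold higher against a floor of 3 counts over the group). That bound rests on the depth of the library labelled HDF whole cell B2. Against whole cell B1 alone it was 3.59-fold. MLPH, melanophilin, had 122 counts against 1, a ratio of 271 (95% counting interval 47.7 to 10790), or 9.38 (1.65 to 374) against whole cell B1 alone. Its call ended regrouped (edgeR adjusted p = 0.0744), and without the library labelled HDF whole cell B2 its log2 fold change was 3.55 ± 1.11 (0.0308). These 2 genes passed without each whole cell library, whereas CMKLR2 (at least 39.2-fold), FEZF2 (38.5-fold), KRT34 (29.6-fold), INSC (28.9-fold), SERPINF1 (ratio 195, interval 34.2 to 7806), AK5 (156, 27.0 to 6227) and LGALS3BP (140, 24.2 to 5613) did not pass when the library labelled HDF whole cell B2 was left out. Against whole cell B1 alone the bounds of CMKLR2, FEZF2, KRT34, INSC and LGALS3BP lay between 0.999 and 1.61, and the ratios were 6.765 (1.18 to 270) for SERPINF1 and 5.38 (0.935 to 216) for AK5. FEZF2 reached 119 and 93.1 CPM in B1 and B2 but 3.02 CPM in B1_2. The 10 genes with the largest losses had 0 counts at HDF focal adhesions. PREX2, a Rac exchange factor, was at least 57.3-fold lower, ATXN1 16.4-fold, TBKBP1 23.6-fold and TNFSF4 21.6-fold, and these 4 passed without each whole cell library. Of the 382, 157 and 144 whole cell counts of PREX2, TBKBP1 and TNFSF4 only 2, 3 and 2 lay in whole cell B1, too few for a bound against it alone. ATXN1 had 12 counts there (at least 52.0-fold). Its call ended relative to genes of its length (edgeR adjusted p = 0.0693). The fitted log2 fold change of ATXN1 went from -8.82 ± 2.19 to -8.73 ± 2.32. With 0 counts at HDF focal adhesions it depends little on the length offset. The call of PREX2 ended regrouped without the library labelled HDF whole cell B2 (edgeR adjusted p = 0.0571). PLCL1 (at least 72.2-fold), PLEKHG1 (53.0-fold), CFAP54 (41.7-fold), TAMALIN (28.4-fold), RNASE1 (25.5-fold) and CABLES1 (21.3-fold) did not pass without the library labelled HDF whole cell B2. Their bounds rest on that library, because each had 1 count in whole cell B1. COL1A1 did not pass (edgeR adjusted p = 0.969) and is given no direction, because it fell by 1.25 ± 0.20 on the log2 scale against whole cell B1 alone (edgeR adjusted p = 3.54e-05) but had 1 count in the library labelled HDF whole cell B2. CDH5 (edgeR adjusted p = 0.179) and PECAM1 (0.147), found at 0 and 1 counts at HDF focal adhesions, did not pass either.

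The second comparison asked how the footprints at focal adhesions differed between the endothelial cells and the fibroblasts. The HUVEC libraries lacked the fibroblast's collagens and carried endothelial junction and receptor mRNAs: COL6A3, a collagen VI chain, had 1 count against 5527 in HDF focal adhesions (5525-fold lower, 95% counting interval 991 to 218300), and CDH5 had 1145 counts against 0 (at least 382-fold higher). Both passed in the fit of only these 2 groups and not in the fit of 3 groups (edgeR adjusted p = 0.394 and 0.281). FN1 was lower in HUVEC focal adhesions at -2.53 ± 0.34 on the log2 scale (SE, n = 2 units; 2037 to 2342 CPM against 9853 to 16149 CPM). MACF1, a giant linker of actin and microtubules, was higher by 3.30 ± 0.47 (4671 to 5298 CPM against 419 to 571 CPM), and SCD was lower at -3.12 ± 0.41 (27.9 to 63.0 CPM against 419 to 490 CPM). G3BP1 lay between 423 and 507 CPM in HUVEC and its difference of 0.12 ± 0.57 did not pass (edgeR adjusted p = 0.953).

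In edgeR's fit of all 3 groups 38 of 8826 genes were higher and 16 lower in HUVEC focal adhesions, and regrouped 7 and 6. That fit shares its spread with the 2 unlike whole cell libraries (common dispersion 0.157). In the fit of only the 2 groups compared, also chosen before the data were examined, the dispersion was 0.0537 and 727 of 7703 genes were higher and 588 lower, including all 38 and 16, while regrouped 428 and 360 passed, of which 416 and 349 were shared. Without the library labelled HDF whole cell B2 the fit of 3 groups called 792 higher and 646 lower, and without whole cell B1 790 and 578. Leaving out any 1 focal adhesion unit left no gene past edgeR's adjusted threshold, with between 376 and 583 higher and between 249 and 523 lower genes at an unadjusted p under 0.05.

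The genes that passed in the fit of 3 groups include the endothelial ribonuclease gene RNASE1 (at least 97.4-fold higher), BST2 (45.0-fold), CCNA1 (43.7-fold), TNFSF4 (34.7-fold), CALCRL, the adrenomedullin receptor (32.4-fold), TSPAN8 (26.7-fold) and CST1 (23.7-fold), all with 0 counts in HDF focal adhesions. APLN, a ligand of endothelial tip cells, had 183 counts against 1 (ratio 183, interval 32.5 to 7270). EVX2 was higher by 6.68 ± 0.73 but unevenly, at 557 and 499 CPM in B1 and B2 and 55.8 CPM in B1_2. GDF15, a stress cytokine, was higher by 5.75 ± 0.86 and HMOX1, heme oxygenase, by 3.06 ± 0.48. Among the losses, WNT5B (ratio 140, interval 24.7 to 5566), CCBE1 (50.0, 16.8 to 245) and SPRY2 (26.7, 8.80 to 132) had between 1 and 3 counts in HUVEC. ITGBL1 was lower at -5.41 ± 0.61, SDC4, syndecan at adhesions, at -4.26 ± 0.51, LTBP1, which binds latent TGF-beta, at -3.28 ± 0.36 and SLC7A2, an arginine transporter, at -3.04 ± 0.42. Of all genes named for this comparison that passed in the fit of 3 groups, only APLN, CCBE1, FN1, GDF15, ITGBL1, LTBP1, MACF1, RNASE1, SCD, TNFSF4 and WNT5B passed regrouped (edgeR adjusted p = 0.0454 each). The others had values between 0.0545 and 0.284, and CST1 was not tested. Of the same genes only EVX2 did not pass in the fit of 2 groups regrouped (edgeR adjusted p = 0.239), CST1 again not being tested.

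Gene groups were counted in the fit of the 2 groups, with the fit of 3 groups beside it. Of the genes whose call is given below from the fit of 2 groups, only ITGB3, KRT18 and SLC2A1 also passed in the fit of 3 groups (edgeR adjusted p between 0.0421 and 0.0423). Of 26 endothelial markers 25 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 8.41e-84; adjusted p = 0.360 with an estimated correlation; 1 higher, and 16 over the list alone, in the fit of 3 groups). By the rule for named genes applied to this fit after its values were seen, RGS5 (at least 370-fold), MMRN1 (346-fold), TIE1 (266-fold), CGNL1 (243-fold), STAB1 (234-fold), NOS3, endothelial nitric oxide synthase (209-fold), ERG and ECSCR (177-fold each) were higher with 0 counts in HDF. Of these, RGS5 is on the smooth muscle and pericyte list, and CGNL1 and STAB1 are on no list. The interleukin-33 receptor gene IL1RL1 had 1875 counts against 1 (ratio 1876, interval 336 to 74130) and PECAM1 815 against 1 (815, 146 to 32240). Of 21 fibroblast markers 2 were higher and 16 lower (3 and 16 over the list alone; camera adjusted p = 1.71e-33; adjusted p = 0.360 with an estimated correlation; 1 and 0, and 2 and 3 over the list alone, in the fit of 3 groups). FBLN1 (at least 269-fold), GREM1 (220-fold), CSPG4 (137-fold), THBS2 (117-fold), CD248 (109-fold) and THY1 (101-fold) had 0 counts in HUVEC. Only FBLN1 and THY1 of these are on the fibroblast list, and CSPG4 is on the smooth muscle and pericyte list. MMP2, which is on the fibroblast list, was higher in HUVEC by 2.94 ± 0.41 in the fit of 3 groups. Of 40 extracellular matrix genes 8 were higher and 22 lower (8 and 23 over the list alone; camera adjusted p = 1.74e-16; adjusted p = 0.394 with an estimated correlation; 2 of 42 higher and 1 lower, and 4 and 5 over the list alone, in the fit of 3 groups). COL1A1 fell to 4 counts, with a log2 fold change of -10.90 ± 0.31 (edgeR adjusted p = 5.35e-14, against 0.448 in the fit of 3 groups), COL1A2 to 3 (ratio 1423, interval 487 to 6903) and COL6A2 to 2 (1981, 548 to 16360). LAMA4 (2.14 ± 0.33) and THBS1 (2.16 ± 0.36) were higher in HUVEC in the fit of 3 groups.

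Cholesterol synthesis was lower in HUVEC focal adhesions, with 10 of 20 genes lower and 16 adjusted over the list alone (shift -1.37, camera adjusted p = 6.78e-09; adjusted p = 0.360 with an estimated correlation). In the fit of 3 groups 2 of 21 were lower, and 9 over the list alone (shift -1.27, camera adjusted p = 5.56e-11; adjusted p = 0.251 with an estimated correlation). In that fit INSIG1, a sterol sensor, was lower at -2.47 ± 0.45. FASN, fatty acid synthase, was lower at -1.49 ± 0.18 in the fit of 2 groups and did not pass in the fit of 3 groups (edgeR adjusted p = 0.122). Of 24 histones 14 were lower and 1 higher (18 and 1 over the list alone; shift -0.67, camera adjusted p = 2.91e-05; adjusted p = 0.360 with an estimated correlation), against 0 and 5 lower over the list alone in the fit of 3 groups and 3 lower regrouped. The linker histone genes H1-3, H1-4 and H1-5 were lower at -1.76 ± 0.23, -1.17 ± 0.20 and -1.08 ± 0.19, and the calls for H1-4 (edgeR adjusted p = 0.0644) and H1-5 (0.0607) ended regrouped. Proliferation had 10 of 36 lower and 0 higher (11 over the list alone; shift -0.47, camera adjusted p = 0.0135; adjusted p = 0.808 with an estimated correlation), including TK1 (-1.47 ± 0.33). In the fit of 3 groups 0 proliferation genes passed, also over the list alone. Of 77 cytosolic ribosomal protein genes 8 were lower (2 over the list alone; shift -0.30, camera adjusted p = 0.0242; adjusted p = 0.360 with an estimated correlation), and 0 passed regrouped.

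Adhesion and cytoskeleton genes went both ways. Of 51 focal adhesion core genes 8 were higher and 7 lower (11 and 7 over the list alone; camera adjusted p = 0.662), with FERMT3, a kindlin of blood and endothelial cells, at 353 counts against 1 (ratio 353, interval 63.0 to 13990) and KANK2 lower at -2.08 ± 0.21. Zyxin (ZYX) was lower at -0.87 ± 0.19 (edgeR adjusted p = 0.00253), a call that ended regrouped (0.121) and in the fit of 3 groups (0.200), and VCL (-0.28 ± 0.20), TLN1 (-0.19 ± 0.17), PXN (0.22 ± 0.25), ITGB1 (0.30 ± 0.17) and ACTB (-0.27 ± 0.17) did not pass. TNS1 was higher by 1.93 ± 0.34 in the fit of 3 groups. Of 11 integrins 5 were higher and 3 lower (5 and 4 over the list alone; camera adjusted p = 0.139), with ITGB3 at 4.10 ± 0.37, ITGA6 at 2.54 ± 0.27 and ITGA2 at 2.18 ± 0.23. Of 12 intermediate filament and linker genes 5 were higher and 3 lower, also over the list alone (camera adjusted p = 0.206), with a median and a mean of opposite sign, including KRT18 (2.45 ± 0.30) and PLEC, plectin (1.39 ± 0.18). Of 39 actin and actomyosin genes 3 were higher and 6 lower, also over the list alone (camera adjusted p = 0.210), the latter including the myosin light chain gene MYL9 (-3.39 ± 0.34) and the tropomyosin gene TPM2 (-2.09 ± 0.22). Microtubules and motors had 3 of 29 higher and 4 lower (5 and 5 over the list alone; camera adjusted p = 0.662), with MAP1B, a microtubule-associated protein, at 1.27 ± 0.17. LRP1, an endocytic receptor, was lower at -6.40 ± 0.41, and the caveolae and endocytosis list had 2 of 25 higher and 4 lower, also over the list alone (camera adjusted p = 0.369).

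Stress granule and RNA-binding proteins had 0 of 46 genes past the test and mitochondrially encoded genes 0 of 13, also adjusted over the list alone, in both edgeR fits (camera adjusted p = 0.662 for each in the fit of 2 groups). G3BP1 (0.08 ± 0.23, edgeR adjusted p = 0.880), G3BP2 (0.21 ± 0.24, 0.658) and CAPRIN1 (-0.38 ± 0.20, 0.227) did not pass. Translation factors had 1 of 38 higher and 4 lower (0 and 1 over the list alone; camera adjusted p = 0.411), with EEF2, the elongation factor, lower at -0.96 ± 0.18. ER genes had 5 of 51 higher and 2 lower (5 and 1 over the list alone; camera adjusted p = 0.662), with the chaperone gene HSPA5 at 0.77 ± 0.17, a call that ended regrouped (edgeR adjusted p = 0.0821) and in the fit of 3 groups (0.444). Immediate early and heat shock genes had 3 of 33 higher and 4 lower (4 and 8 over the list alone; camera adjusted p = 0.676), with CCN2, a target of YAP, at 1.68 ± 0.18. Interferon-stimulated genes had 4 of 11 higher and 0 lower (4 and 1 over the list alone; camera adjusted p = 0.139). In the fit of 3 groups the same list had 1 higher, and 4 over the list alone (camera adjusted p = 0.0169; adjusted p = 0.764 with an estimated correlation). Glycolysis had 0 of 18 higher and 1 lower, SLC2A1 (-2.31 ± 0.31). Nuclear respiratory chain genes had 2 of 47 lower, proteasome genes 1 of 31 lower, tRNA synthetases 2 of 23 higher, chromatin and nuclear factors 3 of 30 higher, protrusion-localised RNAs 3 of 17 higher and 2 lower, and smooth muscle and pericyte markers 1 of 8 higher and 4 lower. Over the list alone these 7 lists had 0 and 1, 0 and 1, 0 and 0, 2 and 0, 1 and 0, 3 and 2, and 1 and 4 genes higher and lower, with camera adjusted p between 0.206 and 0.902.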

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

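The settings with regrouped units and with the coding length trend removed were chosen after the results were seen. Over all settings, 2153 of the values for named genes kept direction and side of the threshold, 902 kept direction only, 67 newly passed and 6 reversed. For list shifts the counts were 999, 75, 30 and 6. Where a setting uses fewer genes or fewer samples that shows in its counts, and the cause was otherwise not tested.

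For HDF focal adhesions against whole cells (400 higher, 520 lower in edgeR) the counts were 1526 and 1633 with limma-voom, 629 and 875 without a filter, 198 higher with the stricter filter, 125 and 217 with only the 2 groups, 635 and 878 with 3 separate samples, 1822 and 1985 with limma-voom and the unit as a random block (correlation -0.235), 245 lower without B1_2, 104 and 171 thinned, 156 and 185 regrouped, and 217 lower with the coding length trend removed. With the transcripts of a gene summed, edgeR called 0 and 0 genes, with 915 and 1232 at an unadjusted p under 0.05. With 1 unit left out at a time, the lone unit taken to vary like the other groups, the counts ranged from 0 to 1327 higher and from 0 to 1476 lower. In DESeq2 357 and 429 genes were called.

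For HUVEC against HDF focal adhesions (38 higher, 16 lower) the counts were 164 and 68 with DESeq2's Wald test, 179 and 110 with limma-voom, 434 and 230 without a filter, 6 lower with the stricter filter, 727 and 588 with only the 2 groups, 365 and 164 with 3 separate samples, 702 and 560 with the random block, 7 and 6 regrouped, 539 and 429 regrouped without the library labelled HDF whole cell B2, and 428 and 360 regrouped with only the 2 groups. Thinned to 92724 counts, edgeR called 1 and 0 genes (257 and 168 at an unadjusted p under 0.05), with 2704 genes tested instead of 8826. With the transcripts of a gene summed it called 0 and 0 (687 and 575 unadjusted). Leaving out 1 unit gave from 0 to 792 higher and from 0 to 646 lower.

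The numbers B1 and B2 did not pair the groups, with correlations of the B1 minus B2 differences between groups of -0.00286, 0.0287 and 0.0589 across 8826 genes. With the number as a replicate block 172 genes were higher and 227 lower in the comparison with whole cells, and 16 and 9 in HUVEC.

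Reversed values, all in the comparison with whole cells, were APLN (2.10 without the library labelled HDF whole cell B2, 2.11 when also regrouped; from -7.31 to 2.10 with 1 unit left out) and SOX7 (2.09 and 2.14; from -8.30 to 2.09), fitted values that then rest on 1 count in all. COL1A1 reversed to 11.67 with the random block, for which the cause was not tested, and ranged from -1.25 to 13.89, the latter against the 1 count of the library labelled HDF whole cell B2. Extracellular matrix reversed to -0.41 without that library (up to 2.38 with another unit left out) and to -0.44 when also regrouped, cytosolic ribosomal proteins to -0.38 without it (up to 0.69) and -0.47 with the length trend removed, fibroblast markers to -0.20 without it (up to 7.37), and chromatin and nuclear factors to 0.41 with the length trend removed. BST2, IFI27, ITGB4 and SOX18 had no counts in either group without that library. Of 26 lists, 18 and 7 passed in the 2 comparisons with camera. With an estimated correlation 0 and 0 passed, with fry 13 and 1, and with the stricter filter 10 in the first.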

Other observations

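The tests of mixed cells, of a swap, of a wrong label for the mitochondrial loss, of the deposited table and of coding length for chromatin genes were chosen only after the results were seen. For the other coding length tests the trend over all genes had been seen but not the list values relative to it.

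The mean of both focal adhesion groups, a comparison added after the results were seen, differed from HDF whole cells in 446 genes that were higher and 667 lower in edgeR. All 13 mitochondrially encoded genes were lower (shift -3.08), 20 of 24 histone genes higher (1.63), 26 of 51 ER genes higher (1.29) and 10 of 21 cholesterol synthesis genes higher (1.67). Of the actin and actomyosin list 11 of 39 were higher and 1 lower. By mean CPM, which is not divided by coding length, AHNAK took the most footprints at focal adhesions of both cell types (mean 18051 CPM, SD 3395, in HDF and 31687, SD 829, in HUVEC; n = 2 units each). In HDF this order was not stable, since MYH9 had a mean of 17591 CPM (SD 19437) and took 41473 CPM in B1_2 against 21972 CPM of AHNAK. In HUVEC AHNAK was followed by the collagenase gene MMP1 (27820 CPM), and in whole cells MT-CO1 took the most (19193 CPM).

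A few genes stood apart in 1 library. MYH9, the heavy chain of non-muscle myosin, took 36939 unnormalised CPM in HDF focal adhesion B1_2 and 3998 in B1 and B2 together, and ALOX12B 2023 and 2.17. In HUVEC B1_2 ONECUT3 stood at 5854 CPM against 6.20. RPS23 was lower in B1_2 in both cell types (689 against 2537 in HDF, 594 against 1985 in HUVEC). The spread of HUVEC B1 against B2 was 3.523, 3.65 and 3.688 times counting noise from the least to the most abundant genes. Against B1_2 the spread rose with abundance, from 2.348 to 11.74 for HUVEC B1 and from 2.097 to 11.97 for HUVEC B2. These values cannot decide whether HUVEC B1 and B2 are separate samples or 1 library.

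The library labelled HDF whole cell B2 carried endothelial transcripts. Fibroblasts mixed with endothelial cells would keep fibroblast transcripts at their share, but the median of 14 fibroblast-side list genes was 9.62e-05 of the level in whole cell B1. A swap with a HUVEC library would need fibroblast transcripts there. Their highest median in a HUVEC library was 0 of the HDF level. The 14 genes had been picked as far lower in HUVEC, so this value was fixed in advance and cannot decide. The whole fibroblast list, fixed beforehand, took between 0.223% and 0.259% of HUVEC focal adhesion libraries and between 1.83% and 2.02% of HDF focal adhesions. These shares argue against a swap with a HUVEC library. Of 299 genes outside all lists that differed at least 16-fold between the cell types, 93.65% lay nearer to HUVEC in the library labelled HDF whole cell B2 and 13.04% in whole cell B1. The library labelled HDF whole cell B2 therefore lacked a fibroblast profile, and endothelial cells under an HDF label are a candidate explanation. Wherever the comparison with whole cells rests on this library, cell type and compartment cannot be told apart.

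Mitochondrially encoded genes were lower at HDF focal adhesions. The tables argue against a wrong label of 1 whole cell library as the cause, since the shift nearest to 0 with either library left out was -3.129, and against coding length, since the shift relative to genes of the same length was -3.429. The sequencing run or deposited table cannot be told apart from the compartment, because 0 groups had libraries in both tables. The compartment, which is what the design compares, stays open as an untested explanation.

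Other list shifts were set against coding length, with which fold changes fell. Relative to genes of the same length the shifts of histones (1.131), cholesterol synthesis (2.586) and ER genes (0.9815) stayed past the camera test and above 0.5 times their size, which argues against the length trend as their whole cause. That camera test used a preset correlation, and with an estimated one these 3 lists did not pass even before the trend was removed (adjusted p = 0.120, 0.186 and 0.228). For chromatin and nuclear factors the shift turned from -0.71 to 0.4105, so coding length may account for that loss. What produces the length trend was not tested, and it cannot be told apart from the deposited table.

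For HUVEC against HDF focal adhesions, the 6 libraries were fitted as separate samples without the whole cell libraries, although B1, B2 and B1_2 may not be independent. Of the 10 splits into 3 and 3, 1 gave as many genes, the real one, with 1063 called against at most 0 in the others. With 10 splits the share cannot fall under 0.05.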
